A study of Homo sapiens with 17 samples.

How the data were processed

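The series holds 17 ChIP-seq samples of A549 cells, a human lung carcinoma line. WT cells gave 2 libraries each of FOXA1, H3K9me3 and H3K27me3 and 1 input, and the A-Fos line gave 2 libraries each of FOXA1 and FOSL2 without and with doxycycline and 2 inputs. The 3 inputs were not analysed here. Groups and replicate numbers were taken from the sample titles, which call the libraries biological replicates. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min, A-Fos was induced with 1 µg/mL doxycycline for 48 h, and libraries were sequenced as paired reads of 50 bp. No library of doxycycline-treated cells lacking A-Fos was analysed here.

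The deposited lists give each peak's position, a linear fold enrichment (a ratio over background) and the −log10 of its p-value and q-value, as the authors' peak caller wrote them. The smallest deposited −log10 q was about 1.30, a q of 0.05. Per the submitters' processing notes, the tools included DRAGEN, fastp 0.23.2, BWA 2.2.1, SAMtools 1.8, deepTools and MACS2, and the build was hg38; their order and settings are not given in the sources used here. There was 1 list per library, so peaks were not called on pooled replicates. Peak numbers ran without gaps in the WT lists, while 30 to 172 numbers were missing from each A-Fos list, for a reason not given in the sources used here. The lists hold no read counts, so depth is unknown, no count-based precision can be given, and a longer list can come from a deeper library. Fold enrichments are the authors' own and were used to rank peaks within a list.

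Peaks on chromosomes 1 to 22 and X were kept. For each factor, peaks of the 4 A-Fos lists that overlapped by at least 1 bp were merged into regions. A region was lost when called in both libraries without doxycycline and neither with it, kept when called in all 4, and gained in the opposite case. Regions called in other combinations of libraries, 46365 of 56430 for FOSL2 and 21469 of 27825 for FOXA1, were given no class. Regions merged over 2 lists differ slightly in number from those merged over 4, so 6015 and 6012 FOXA1 regions were called in both libraries without doxycycline. A region was bound by FOSL2 when it overlapped by at least 1 bp a FOSL2 region called in both libraries without doxycycline. A histone mark was taken where both libraries covered it.

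Shares have 95% exact (Clopper-Pearson) intervals, which cover counting error over regions alone. Odds ratios were tested with Fisher's exact test and strata were combined by the Mantel-Haenszel method. Overlaps were compared with 1000 circular shifts along each chromosome, ranks with 100000 permutations that kept ties, and peak numbers with exact permutation tests. Gene lists were compared with all other protein-coding genes (marks) or with genes that had a lost or kept region within 50 kb (binding), with Benjamini-Hochberg adjustment over 14 lists or 28 list and mark pairs.

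Gene intervals came from a GRCh38.p14 table of 19970 protein-coding genes without strand. The planned windows around transcription start sites were therefore replaced by 50 kb around the gene and 1 kb around either end, and regions were named by the nearest gene interval. The planned comparison of AP-1 and forkhead motifs needed a genome sequence, which was not used here. Exons and introns were not distinguished.

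The rule for named genes, the lists, the alternatives and the tests of the report's comparisons were fixed before the data were examined. The exceptions were the replaced windows and the factor shifted for the overlap of FOXA1 and FOSL2, planned as FOSL2. The closing section names the tests chosen afterwards. The rule took the 6 regions per class with the highest mean percentile of enrichment (doxycycline lists for gained FOXA1 and kept FOSL2 regions), each nearest gene once, the 10 genes of at least 5 kb most covered by each mark, up to 6 members per state of each list as examples, and always FOXA1, FOSL2, FOS and JUN. Among the 10 genes per mark, the number sharing a gene family prefix was capped, and ties in coverage went to the longer gene. ZNF10, PAX7, OTX2, HOXD13, MYOD1, SYN1, CD34 and MMP9 were chosen as mark examples after their values were seen. The 14 lists were lung epithelial, AP-1 family, AP-1-linked, NRF2 target, liver and foregut, steroid response, developmental regulator, zinc finger, olfactory receptor, protocadherin, housekeeping, blood, neuron and muscle, and fibroblast and endothelial genes.

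Alternatives were the upper part of each list by enrichment, lists of equal length, 200 bp around each summit, 50% coverage without merging, all contigs, each library left out, a replicate block, strata of enrichment, regions over 1 kb from gene ends, other windows, joined marks and random placement.

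Interval, odds ratio and rank functions were tested on simulated data. In 20 simulated sets of FOXA1 regions with a true odds ratio of 2.27 the median estimate was 2.26, and all 20 intervals held the true value. In random labellings the rank test gave p under 0.05 in 9 of 200 for a list with many ties and in 3 of 200 for a WT FOXA1 list. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.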

Results

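The series profiled protein binding and histone marks by chromatin immunoprecipitation with sequencing (ChIP-seq) in A549, an established human lung carcinoma line. In unmodified (WT) cells the targets were FOXA1, a forkhead pioneer factor of lung and liver epithelium, and the repressive histone marks H3K9me3 and H3K27me3, with 2 libraries each. In a derived line carrying a doxycycline-inducible A-Fos, a dominant-negative form of Fos that disables AP-1 dimers, the targets were FOXA1 and the AP-1 subunit FOSL2, with 2 libraries without and 2 with doxycycline (1 µg/mL for 48 h). The 14 lists analysed held 49448 and 80318 FOXA1 peaks in WT cells, 305084 and 201740 H3K9me3 peaks and 190938 and 228427 H3K27me3 peaks, counted on chromosomes 1 to 22 and X. Sequencing depth per library cannot be read from peak lists, so differences in list length also carry differences in depth and antibody yield. Regions are the units of the tests over regions and are not independent replicates, so those p-values describe these lists.

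The first comparison asked what induction of A-Fos did to FOSL2 binding. FOSL2 peaks fell from 45586 and 14842 without doxycycline to 1854 and 5274 with it, or from 30214 ± 21739 to 3564 ± 2418 (mean ± SD, n = 2 each), a ratio of 0.118. The strongest enrichment in a list, as the authors' peak caller gave it, was 148-fold and 45.9-fold without doxycycline and 6.57-fold and 6.78-fold with it. Of 10191 regions called in both libraries without doxycycline, 10030 (98.4%) were called in neither library with it, and 10 were called in all 4. Another 25 regions were called only in both doxycycline libraries. Splitting the same 4 libraries by replicate number gave 120 and 272 such regions, and the crossed split gave 163 and 39. These splits need a call in a doxycycline list, and no such list shared more than 395 regions with one without doxycycline. Their counts could therefore not approach 10030 and give no noise rate for the loss.

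The lost FOSL2 regions of highest enrichment lay both outside and inside genes. The nearest genes were ACTBL2, an actin-like gene (chromosome 5, 57692993 to 57693638, 210 kb away), the olfactory receptor gene OR5AK2 (chromosome 11, 56932610 to 56933347), FSCB, a sperm fibrous sheath gene (chromosome 14, 44316506 to 44317511), and ANKRD10 (chromosome 13, 110964836 to 110965822). Others lay inside CRADD, a death-domain adaptor (chromosome 12, 93785118 to 93785884), and SHTN1, shootin (chromosome 10, 116946728 to 116947604). The FOSL2 gene itself had a lost FOSL2 region 28.5 kb away and JUN, which encodes an AP-1 partner, had one 24.9 kb away. Neither FOS nor FOXA1 had a lost, kept or gained FOSL2 region within 50 kb, but regions without a class were not searched. Of the regions called in all 4 libraries, that nearest PDE3A, a cyclic nucleotide phosphodiesterase gene, stood at the 99.4 and 99.6 percentiles of enrichment without doxycycline and at the 71.4 and 58.2 percentiles with it. Those nearest TUBA3C, a tubulin gene, and MEX3B, an RNA-binding protein gene, stood at the 13.9 and 2.42 percentiles and at the 31.1 and 9.94 percentiles without it. The remaining named regions of this class were nearest UQCRFS1, FOXD4L6 and GKAP1. Among genes with a lost or kept FOSL2 region within 50 kb, every member of the 13 lists that held such genes had a lost one, as did 99.97% of other genes, which left no room for a list to differ.

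The fall in FOSL2 peaks had an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries allow. Without the second library lacking doxycycline, 45139 regions were lost, and with either doxycycline library alone the gained regions rose to 4705 and 1615 and the kept regions to 111 and 59, against 19 and 17 kept with either library lacking doxycycline left out. With lists of equal length 1264 regions were lost and 0 kept, with the upper part of each list 8 were gained and 1 kept, and with all contigs 34 were kept.

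**Figure D1:**
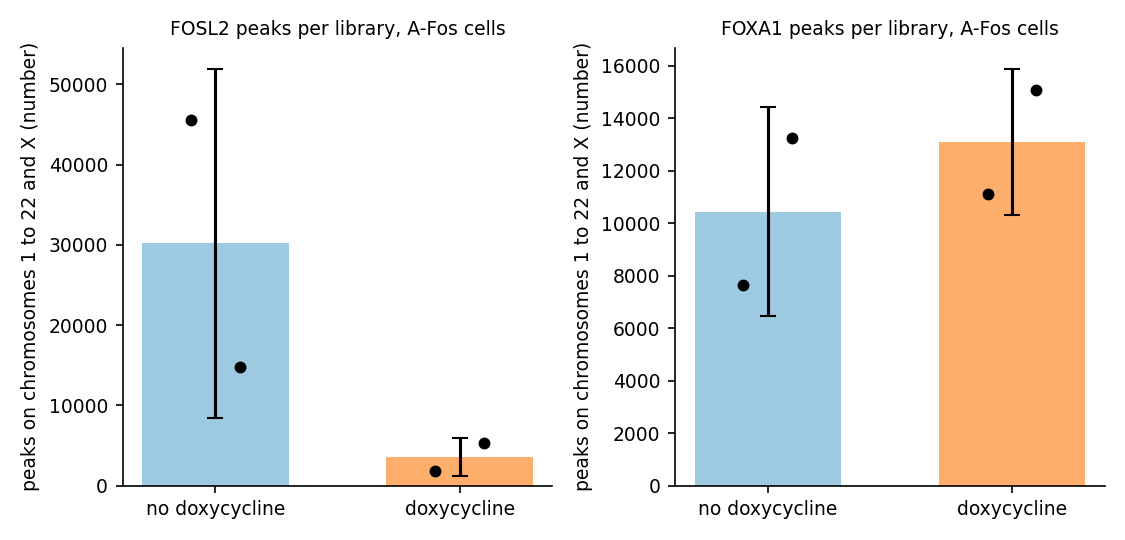
Peaks per library (vertical axis, number on chromosomes 1 to 22 and X) for FOSL2 (left) and FOXA1 (right) in A-Fos cells without and with doxycycline; bars are means, error bars SDs and points the 2 libraries of each condition. Both FOSL2 libraries with doxycycline (1854 and 5274) lie below both without it, while the FOXA1 libraries of the conditions interleave.

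The second comparison asked what the same induction did to FOXA1 binding. FOXA1 peaks numbered 7633 and 13247 without and 11112 and 15065 with doxycycline, 10440 ± 3970 against 13088 ± 2795 (mean ± SD, n = 2 each), and the libraries of the conditions interleaved in peak number (exact two-sided permutation p = 0.667, where 2 against 2 libraries allow no p below 0.333). The strongest enrichment was 110-fold and 162-fold without doxycycline and 109-fold and 176-fold with it. Median enrichment did not interleave, at 5.74-fold and 6.34-fold without doxycycline and 4.48-fold and 4.75-fold with it. Whether the lower medians affected the lost and gained calls was not tested. Of 6012 regions called in both libraries without doxycycline, 3205 (53.3%) were called in all 4 libraries and 1872 (31.1%) in neither doxycycline library. A further 1279 regions were called in both doxycycline libraries and neither of the others. The split by replicate number gave 132 and 1210 regions, so its larger arm was close to the count of gained regions, and the crossed split gave 88 and 285.

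FOXA1 regions that also carried FOSL2 before induction were lost more often. A FOSL2 region overlapped 755 of 1872 lost FOXA1 regions (40.3%, 95% exact interval 38.1 to 42.6), 665 of 3205 kept regions (20.7%, 19.4 to 22.2) and 9 of 1279 gained regions (0.704%, 0.322 to 1.33). The odds ratio of FOSL2 overlap was 2.58 (2.28 to 2.93) for lost against kept regions (Fisher's exact test, two-sided, p = 9.10e-50) and 0.0271 (0.0140 to 0.0524) for gained against kept regions (Fisher's exact test, two-sided, p = 1.12e-91). FOSL2 also overlapped 53 of 1210 regions (4.38%, 3.30 to 5.69) called in both libraries numbered 2 and in neither numbered 1. In that comparison, chosen afterwards, each side holds 1 library with and 1 without doxycycline. A share below that of kept regions thus also appeared without a doxycycline contrast. In the lowest decile of FOXA1 enrichment 81.7% of regions with FOSL2 and 48.5% of those without were lost, and in the highest decile 10.5% and 5.19%. Loss was 53.2% where a FOSL2 region overlapped, 32.5% where the nearest was within 1 kb, 27.6% at 1 to 10 kb and 31.1% with none within 10 kb.

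The strongest lost FOXA1 regions with FOSL2 lay inside PLCB1, a phospholipase C gene (chromosome 20, 8156424 to 8157271), BCCIP, whose product binds BRCA2 (chromosome 10, 125840823 to 125841474), and AUTS2, a neurodevelopmental gene (chromosome 7, 70571248 to 70571798). Others were nearest ZNF608, PTGER4, a prostaglandin E receptor gene, and IPMK, an inositol phosphate kinase gene. Lost regions without FOSL2 lay inside DIS3L2, a 3′ to 5′ exoribonuclease gene, IFT80, a ciliary transport gene, DST, which encodes the cytoskeletal linker dystonin, and NHS, or nearest the cadherin gene CDH6 and ACTBL2. All stood above the 95th percentile of enrichment in both libraries without doxycycline. The strongest kept region lay 53.2 kb from IL6, the interleukin 6 gene (chromosome 7, 22672975 to 22674052), and overlapped FOSL2. Other kept regions lay inside ITPR2, a calcium channel gene of the endoplasmic reticulum, TRIM6-TRIM34, and LTBP1, a latent TGF-β binding protein gene, or nearest SLC38A2, an amino acid transporter gene, and BICC1, an RNA-binding protein gene. Gained regions lay inside TXNRD1, which encodes thioredoxin reductase (chromosome 12, 104307142 to 104307746), CSMD2 and NCEH1, a cholesterol ester hydrolase gene, or nearest AKIRIN1, the BMP regulator gene BMPER and the opioid receptor gene OPRK1. None of these 6 gained regions overlapped FOSL2.

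Among genes with a lost or kept FOXA1 region within 50 kb, 6 of 11 lung epithelial genes had a lost one and 9 a kept one. FOXA1 itself had a kept region 42.1 kb away at the 97.3 percentile, and SCGB3A2, a secretoglobin gene of airway cells, and GRHL2, an epithelial transcription factor gene, had kept regions at the 99.9 and 98.9 percentiles. SFTPB, a surfactant protein gene, had 2 lost regions and no kept one. Of AP-1-linked matrix, adhesion and growth factor genes 6 of 17 had a lost region: CCND1, the cyclin D1 gene, had one 0.21 kb away that overlapped FOSL2, while the chemokine gene CXCL8, the growth factor receptor gene EGFR and CCN2 had kept regions at the 97.7, 98.2 and 96.8 percentiles. EGFR also had 2 lost regions, the stronger at the 56.3 percentile and overlapping FOSL2. A lost region lay near 2 of 5 AP-1 family genes, among them BATF, and JUN had a kept one. The counts were 3 of 9 for NRF2 targets, with kept regions at ME1 and AKR1C2, of which AKR1C2 also had a lost one, 3 of 9 for liver and foregut genes, 3 of 4 for steroid response genes, 5 of 9 for developmental regulators, 15 of 36 for zinc finger genes and 7 of 17 for olfactory receptors. They were 0 of 5 for housekeeping genes, 1 of 2 for blood markers, 3 of 6 for neuron and muscle markers and 2 of 3 for fibroblast and endothelial markers. None of these 13 lists differed from other genes (adjusted p of 0.508 or 1, Fisher's exact test, Benjamini-Hochberg over 14 lists), nor did any with windows of 10 or 100 kb (adjusted p from 0.158 to 1). At 10 kb the share changed side against other genes for lung epithelial (3 of 8), AP-1 family (2 of 2), steroid response (1 of 3), zinc finger (7 of 12) and fibroblast and endothelial genes (0 of 1), and was 0 of 7 for NRF2 targets, 1 of 7 for liver and foregut genes and 0 of 4 for olfactory receptors. At 100 kb it changed side for AP-1-linked (11 of 20), developmental (7 of 19), zinc finger (31 of 68), olfactory receptor (16 of 34) and blood genes (1 of 3), and was 1 of 6 for housekeeping genes. All 38 protocadherin genes had a lost region against 43.1% of other genes (adjusted p = 2.25e-13, Fisher's exact test), but these genes share a cluster on chromosome 5 and the count rests on 2 distinct lost regions (141003939 to 141004528 and 141521094 to 141521576), both overlapping FOSL2.

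Without the first or the second FOXA1 library lacking doxycycline 6342 and 3109 regions were lost; without the second 2503 were gained, and without the first or the second doxycycline library 8585 and 5744 were; with the upper part of each list 1005 were lost and 2068 kept. The odds ratio for lost regions was 1.52 without the second FOXA1 library and 3.88 without the second FOSL2 library lacking doxycycline, and that for gained regions was 0.0459 and 0.134 without either FOXA1 library lacking doxycycline, 0.0667 without the second doxycycline library, 0.0492 and 0.0754 without either FOSL2 library, 0.0678 with the upper part of each list and 0.0606 around summits. Induction of A-Fos and exposure to doxycycline changed together in all libraries.

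**Figure D2:**
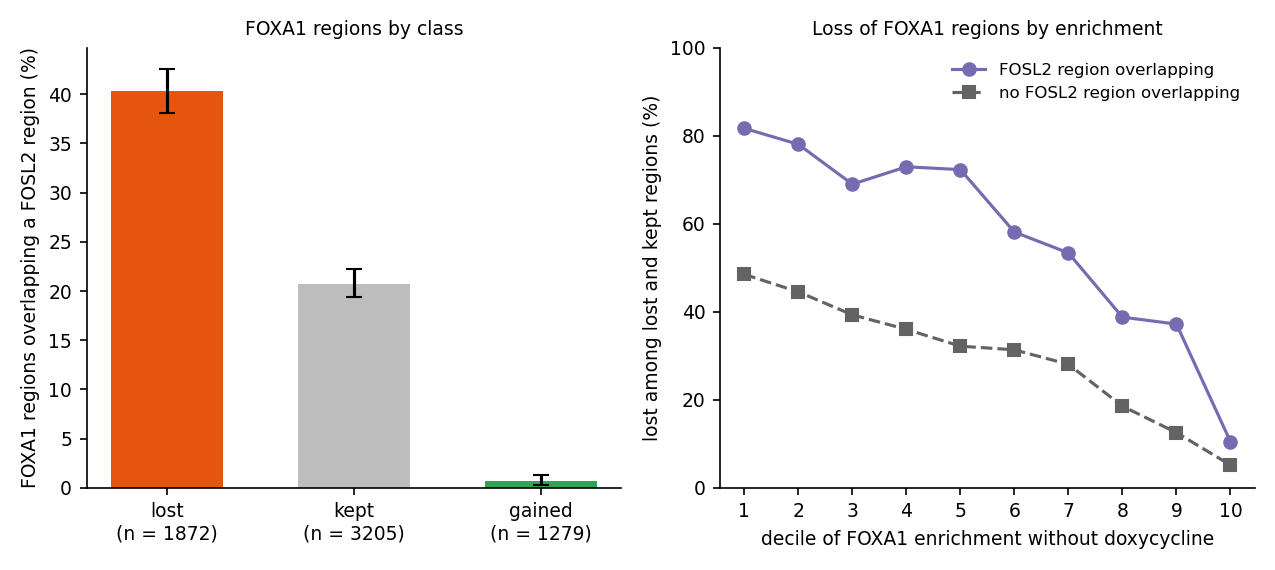
Left, share of lost, kept and gained FOXA1 regions that overlapped a FOSL2 region called in both libraries without doxycycline (%, bars, with 95% exact intervals). Right, share of lost regions among lost and kept ones (%) by decile of FOXA1 enrichment without doxycycline, for regions with and without an overlapping FOSL2 region; the values with FOSL2 lie above those without it in all 10 deciles.

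The reverse comparison asked whether FOSL2 regions at FOXA1 were lost at another rate. FOXA1 overlapped 1651 of 10030 lost FOSL2 regions (16.5%, 95% exact interval 15.7 to 17.2) and 4 of 10 kept regions (40%, 12.2 to 73.8). The odds ratio was 0.296 (0.0833 to 1.05; Fisher's exact test, two-sided, p = 0.0673), which did not pass 0.05. Among the kept regions that nearest TUBA3C overlapped FOXA1 and those nearest PDE3A, MEX3B, UQCRFS1, FOXD4L6 and GKAP1 did not. With 10 kept regions the call depended on the setting: the odds ratio was 0.904 without the first doxycycline library of FOSL2, 0.308 without the second (p = 5.34e-05, Fisher's exact test) and 0.274 without the second library lacking doxycycline (p = 0.0385, Fisher's exact test). It also passed 0.05 around summits (0.118), with 50% coverage (0.196) and with all contigs (0.281) by Fisher's exact test. Within deciles of enrichment (0.276) it passed by the Mantel-Haenszel method. With all contigs, 24 of the 34 kept regions lay on contigs outside the chromosomes analysed. With a replicate block the direction reversed, at an odds ratio of 1.25 (0.981 to 1.59) by the Mantel-Haenszel method. The direction of the difference thus also depended on the setting.

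Before induction FOXA1 and FOSL2 shared many regions. Of 6015 FOXA1 regions called in both libraries 1699 (28.2%, 95% exact interval 27.1 to 29.4) overlapped a FOSL2 region, as did 1685 of 10190 FOSL2 regions (16.5%, 15.8 to 17.3) a FOXA1 region. Circular shifts of the FOXA1 regions along each chromosome gave 0.414% ± 0.0855 (SD over 1000 shifts), a 68.3-fold difference (permutation p = 0.002, the smallest that the shifts can give). The shifts place regions anywhere along a chromosome, whether or not a factor can bind there. The fold therefore cannot separate an association of FOXA1 with FOSL2 from a preference of both for the same accessible parts. Shared regions included those nearest IL6 and inside LTBP1, PLCB1, BCCIP and AUTS2. The fold was 144 around summits and 38.6 without the second FOSL2 library, where 58.6% of FOXA1 regions overlapped.

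The parent and the engineered cells shared most FOXA1 regions of the engineered ones. Of 6015 A-Fos regions without doxycycline, 5972 (99.3%, 95% exact interval 99.0 to 99.5) were among the 35739 WT regions called in both libraries, while 16.6% of WT regions were called in A-Fos cells. The share rose from 0.112% in the lowest decile of WT enrichment to 86.1% in the highest. With lists of equal length 81.4% of A-Fos and 67.7% of WT regions were shared. The WT share was 33.2% without the first A-Fos library and 7.39% without the first WT library.

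**Figure D3:**
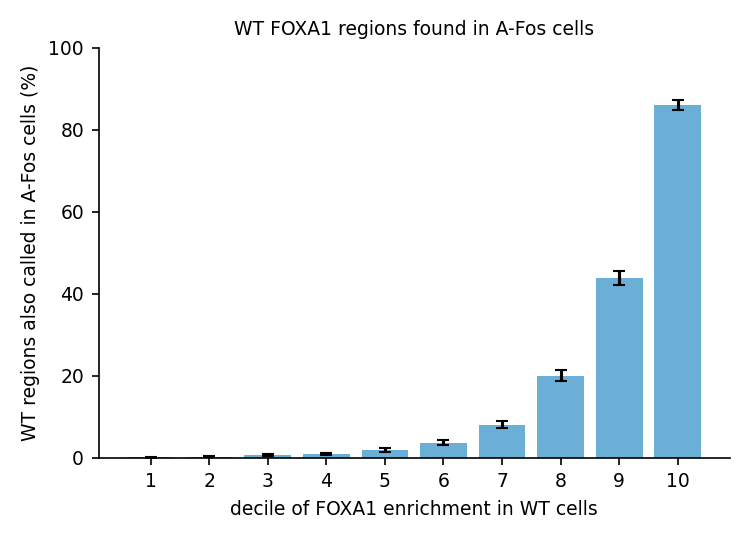
Share of WT FOXA1 regions that were also called in A-Fos cells without doxycycline (vertical axis, %, with 95% exact intervals) by decile of enrichment in WT cells (horizontal axis). The share is 0.112% in the lowest and 86.1% in the highest decile.

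In WT cells FOXA1 regions and the repressive marks lay mostly apart. H3K9me3, a mark of constitutive heterochromatin, overlapped 698 of 35739 FOXA1 regions (1.95%, 95% exact interval 1.81 to 2.10) against 6.84% ± 0.212 after circular shifts, 0.286 times that level. H3K27me3, the mark set by Polycomb repressive complexes, overlapped 1154 (3.23%, 3.05 to 3.42) against 8.69% ± 0.303, or 0.372 times (both with a two-sided permutation p of 0.002, the smallest that 1000 shifts can give). FOXA1 peaks inside H3K9me3 had a lower enrichment rank, with a median percentile of 16.7 against 51.4 outside in the first library and 31.5 against 51.2 in the second. Inside H3K27me3 the medians were 22.8 against 51.4 and 33.1 against 51.2 (permutation test, p = 1e-05 in all 4 tests, the smallest that 100000 resamples can give). The marks covered 102 and 148 Mb in both libraries and shared 10.2 Mb, 1.52 times the 6.71 Mb of shifted marks. The shared length was 24.7 Mb (2.02 times the shifted level) without the second and 14.3 Mb (1.31 times) without the first H3K9me3 library, where H3K9me3 covered 195 and 178 Mb. It was 15.6 Mb (1.44 times) without the first H3K27me3 library, where H3K27me3 covered 258 Mb, 5.16 Mb (1.31 times) with the upper part of each list and 64.7 Mb (1.41 times) with the joined marks of either library. Without the second WT FOXA1 library 3.38% of FOXA1 regions overlapped H3K9me3 and 5.10% H3K27me3, with ratios of 0.604 and 0.686. The share in H3K9me3 was 3.63% and 3.41% without the first and the second library of the mark, and that in H3K27me3 was 5.46% without its first library. With joined marks the shares were 5.22% and 6.55%, and with the upper part of the H3K9me3 lists 1.27%.

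The H3K9me3 mark lay within 1 kb of an end of 1822 of 19970 protein-coding genes (9.12%) and H3K27me3 at 4644 (23.3%). Without the second H3K9me3 library the first of these counts was 3086 (15.5%). H3K9me3 marked 342 of 517 zinc finger genes (66.2% against 7.61% of other genes, adjusted p = 3.54e-232), 47 of 53 protocadherin genes (88.7%, adjusted p = 1.45e-41) and 85 of 392 olfactory receptor genes (21.7%, adjusted p = 1.98e-13, all by Fisher's exact test over 28 tests). Without the second H3K9me3 library 155 olfactory receptor genes carried it (39.5%), and with 5 kb around gene ends 160 did. Under the cap per gene family, the genes most fully covered were the zinc finger genes ZNF671, ZNF132 and ZNF256 on chromosome 19. H3K9me3 covered 100%, 100% and 99.8% of these genes. Next came ANHX, ZIK1, ZFP3, PPP2R1A, which encodes a scaffold subunit of protein phosphatase, ZSCAN1, MSANTD5 and C19orf18. Further ZNF genes were left out by the cap and may stand between them. ZNF10 was covered over 84.1% of its length. The other 11 lists did not differ from other genes in H3K9me3 (adjusted p from 0.205 to 1, Fisher's exact test), with 0 of 31 lung epithelial, 0 of 14 AP-1 family, 4 of 36 AP-1-linked, 2 of 18 NRF2, 1 of 20 liver and foregut, 1 of 15 steroid response and 6 of 83 developmental genes marked. No housekeeping, blood or neuron and muscle gene carried it, and 2 of 14 fibroblast and endothelial genes did. Without the second H3K9me3 library 17 of 83 developmental, 4 of 31 lung epithelial, 2 of 14 blood, 2 of 20 liver and foregut, 1 of 14 AP-1 family and 1 of 15 neuron and muscle genes carried it. The developmental share (20.5%) then lay above that of other genes (15.4%) and not below it, while those of AP-1-linked genes (5 of 36) and NRF2 targets (2 of 18) lay below and not above. Without the first library 2 of 31 lung epithelial and 1 of 14 blood genes did. With 5 kb around gene ends 1 to 14 genes of each of these 11 lists carried it, and in none of these settings did one of the 11 pass 0.05 (Fisher's exact test).

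H3K27me3 lay at 43 of 83 developmental regulators (51.8% against 23.1% of other genes, adjusted p = 1.02e-07 by Fisher's exact test), among them OTX2, HOXD13 and PAX7, transcription factor genes of head, limb and muscle development. It marked 145 of 392 olfactory receptor genes (37.0%, adjusted p = 4.07e-09), 10 of 15 neuron and muscle markers (adjusted p = 0.0017), including the muscle regulator gene MYOD1 at 83.7% of its length and SYN1, and 8 of 14 blood markers, including CD34 (adjusted p = 0.0222, all by Fisher's exact test). It was rarer at zinc finger genes (43 of 517, adjusted p = 3.10e-18), housekeeping genes (0 of 20, adjusted p = 0.0222), AP-1-linked genes (2 of 36, adjusted p = 0.0254), NRF2 targets (0 of 18, adjusted p = 0.0295) and protocadherin genes (5 of 53, adjusted p = 0.033, all by Fisher's exact test). The result for AP-1-linked genes ended without the first H3K27me3 library (8 of 36, adjusted p = 0.568, Fisher's exact test) and with 5 kb around gene ends (8 of 36, adjusted p = 0.179). That for protocadherin genes ended without the second library (7 of 53, adjusted p = 0.0866, Fisher's exact test) and with 5 kb (15 of 53, adjusted p = 0.332), while zinc finger genes still passed at 71 of 517 without the first library and 126 with 5 kb. With 5 kb 5 of 14 AP-1 family, 6 of 20 liver and foregut and 1 of 20 housekeeping genes carried it, and without the first library 5 of 20 liver and foregut genes did. Among AP-1 family and AP-1-linked genes MMP9, a matrix protease gene, was covered over 70.0% of its length and FOS over 54.1%, whereas JUN, FOSL2 and FOXA1 carried neither mark. Lung epithelial genes (10 of 31), AP-1 family genes (2 of 14), liver and foregut genes (3 of 20), steroid response genes (7 of 15) and fibroblast and endothelial markers (7 of 14) did not pass (adjusted p from 0.0565 to 0.737, Fisher's exact test), although fibroblast and endothelial markers passed without the second library (8 of 14, adjusted p = 0.0317). Genes fully covered in both libraries included PDYN, which encodes the opioid precursor prodynorphin, and the immune receptor genes CD300E and CD300LB. Others were the cytochrome P450 genes CYP2A13, CYP2A6 and CYP11B1, the kallikrein genes KLK10, KLK2 and KLK3, and the keratin gene KRT9. These were the longest such genes under the cap per gene family, so further genes may be fully covered too. Zinc finger, olfactory receptor, protocadherin and HOX genes lie in clusters, so neighbouring genes are not independent and these p-values are too small.

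**Figure D4:**
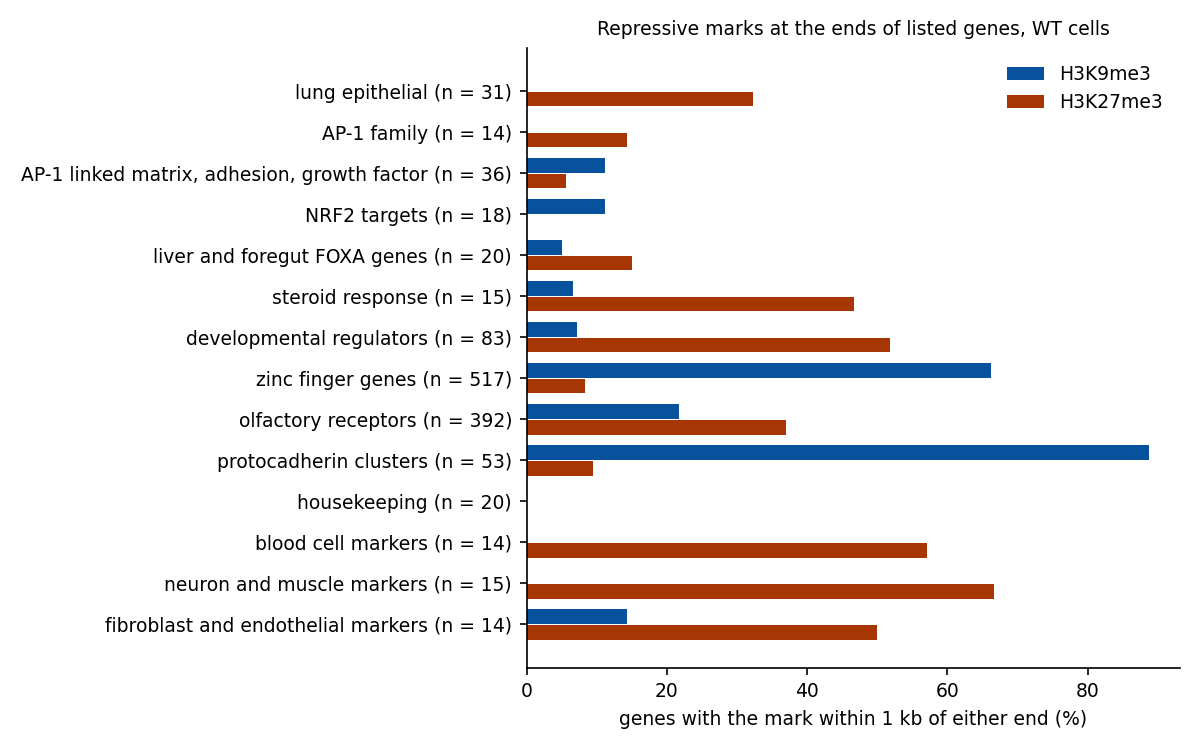
Share of the genes of each list (vertical axis, number of genes in parentheses) that had H3K9me3 or H3K27me3 within 1 kb of either end in both WT libraries (horizontal axis, %). H3K9me3 reached 88.7% of protocadherin and 66.2% of zinc finger genes, and H3K27me3 66.7% of neuron and muscle markers and 51.8% of developmental regulators.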

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

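The test of whether FOSL2 moved to other sites was chosen after the result was seen, and the other tests in this part before.

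The number of FOSL2 peaks with doxycycline was 0.0407 and 0.355 times that without it in the libraries numbered 1 and 2, while for FOXA1 the ratios were 1.46 and 1.14. These stood out because both ratios of FOSL2 lay below 1 and both of FOXA1 above 1. Nothing in the labels ties equal numbers to a common batch, so the pairing is arbitrary. For FOSL2 both lists with doxycycline were shorter than both without it under either pairing. For FOXA1 the direction depends on the pairing, since the first list with doxycycline (11112 peaks) was shorter than the second without it (13247). The difference was not tested, and depth per library is unknown.

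On contigs outside chromosomes 1 to 22 and X, which the comparisons left out, 24 FOSL2 regions were called in all 4 libraries, against 10 on the chromosomes analysed. They were 70.6% of all FOSL2 regions kept, while 0.139% of lost FOSL2 regions lay there.

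FOXA1 regions lost with doxycycline overlapped FOSL2 more often than kept ones. Loss of weaker regions at the calling threshold was argued against by an odds ratio of 3.75 (3.25 to 4.32) within deciles of FOXA1 enrichment. With lists of equal length the odds ratio was 3.25 (2.44 to 4.31). The FOSL2 lists were then cut too, to 1854 peaks each. This argued against FOXA1 list length for overlap with the strongest FOSL2 regions, and for the other FOSL2 regions list length stays open. A change of the wider neighbourhood, such as copy number, was argued against since a FOSL2 region 1 to 10 kb away gave 0.844 (0.699 to 1.02), with its upper bound below the interval for overlap, whose odds ratio was 2.51. A candidate explanation that remained is FOXA1 binding that leans on AP-1: regions in the highest quintile of FOSL2 enrichment were lost more often than those in the lowest, with an odds ratio of 3.68 (2.44 to 5.53) within tertiles of FOXA1 enrichment. Without the tertiles, loss from the lowest to the highest quintile was 40.85%, 51.8%, 51.8%, 62.3% and 59.2%, so it did not rise at every step. An effect of doxycycline itself stays open, and so does FOXA1 signal carried by neighbouring AP-1, which the lists could not test.

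FOSL2 calls with doxycycline rarely coincided, with 54 regions in both libraries. Whether FOSL2 moved to another set of sites stays open: of the regions of the shorter list in neither list without doxycycline, 1.55% (1.00 to 2.28) were in the longer list, against 16.9% (8.44 to 29.0) of those in both lists without it, but the small overlap itself keeps the first share low and the second set was picked from repeatedly called regions. Weak background calls cannot be told apart from weak binding: calls shared with another FOSL2 list had a median percentile above that of unshared calls by 0 in the first library and by 8.13 in the second, and tied enrichments keep the first difference at 0. The biological explanation given by the design, removal of FOSL2 by A-Fos, stays open beside it.

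FOXA1 lists of WT cells were several times longer than those of A-Fos cells. The additional WT regions may mostly be the weaker ones, since the share found in A-Fos cells was higher by 86.0 percentage points in the top than in the bottom decile of WT enrichment. Depth, batch and the cell line itself were not tested and stay open.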

How the results depend on the processing

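No test in this part was chosen after the results were seen. Of the alternative values of comparisons 114 kept their direction and side of the threshold (counts within 1.5 times), 25 moved, 6 came to pass the threshold and 1 reversed. Shares of A-Fos FOXA1 regions found in WT cells were judged more narrowly, and 99.5% against 99.3% counted as moved. Gene lists were judged by the number past the threshold, so an exchange of lists counted as the same. For H3K27me3 that number was 9 with and without its second library, although protocadherin genes left and fibroblast and endothelial markers entered. Of the alternative values of the 36 named regions 242 were the same and 10 moved, all at kept FOSL2 regions. Leaving out a library gave no test here, since a region called in all libraries of a condition, or in none, stays so. Cuts by enrichment could hardly move the named lost and gained regions, which were picked for high enrichment. FOXA1 loss at FOSL2 kept its direction and stayed below p = 0.05 (Fisher's exact or Mantel-Haenszel test) in every alternative, from 1.52 to 3.88, as did both overlaps of FOXA1 with marks (permutation by shifts or random placement).

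With the upper part of each list, 8 FOSL2 regions were gained and 1 kept, and 1005 FOXA1 regions lost and 2068 kept. With equal lengths 1264 FOSL2 regions were lost and 0 kept, and with all contigs 34 were kept. Leaving out one library gave 10079 to 45139 FOSL2 regions lost, 33 to 4705 gained and 17 to 111 kept, and 2216 to 6342 FOXA1 regions lost, 1431 to 8585 gained and 3356 to 4431 kept, since a condition then rests on 1 list. The share of A-Fos FOXA1 regions found in WT cells was 100% with the upper part of each list, 96.8% around summits, 81.4% with equal lengths and 86.5% to 99.5% with a library left out. FOSL2 loss at FOXA1 had an odds ratio of 0.118 around summits, 0.196 with 50% coverage, 0.281 with all contigs and 0.276 within deciles, each past the threshold (Fisher's exact test or Mantel-Haenszel), and 0.274 to 0.904 with a library left out; the cause was not tested.

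The titles share replicate numbers, which nothing in the labels ties to a common batch. Deviations of same-numbered libraries correlated at 0.164 for FOSL2 and 0.0166 for FOXA1 over regions. With a replicate block the odds ratios were 1.61 for FOXA1 loss, 0.136 for FOXA1 gain and 1.25 for FOSL2 loss at FOXA1, which reversed; counts of lost regions, 10030 and 1872, and gained regions, 25 and 1279, are the same by construction.

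Odds ratios from counts with an empty cell were not recorded and are not among the alternative values counted above. This left none for FOXA1 gain with equal lengths or for FOSL2 loss at FOXA1 with equal lengths or the upper part of each list. In the upper part the 1 kept FOSL2 region, nearest PDE3A, did not overlap FOXA1. That odds ratio was therefore unbounded and opposite in direction to the main one. The motif comparison was not run. Depth per library is unknown, which limits every count of lost and gained regions.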

Other observations

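All comparisons in this part were chosen after the results were seen.

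FOXA1 regions gained with doxycycline lay in repressive marks of WT cells more often than kept ones. H3K27me3 overlapped 142 of 1279 gained regions (11.1%, 95% exact interval 9.43 to 12.9) against 52 of 3205 kept (1.62%) and 9 of 1872 lost regions (0.481%). The odds ratio of gained against kept regions was 7.57 (5.47 to 10.5, adjusted p = 4.28e-39, Fisher's exact test) and 7.91 (4.98 to 12.6) within deciles of enrichment in the doxycycline lists. Regions called in both libraries numbered 2 and in neither numbered 1 served as a comparison in which each side holds 1 library with and 1 without doxycycline: 3.72% (2.73 to 4.94) lay in H3K27me3. H3K9me3 overlapped 4.14% of gained and 1.03% of kept regions, but also 5.37% (4.17 to 6.80) of those in the comparison by number. FOSL2 overlapped 0.704% of gained and 20.7% of kept regions, and 4.38% (3.30 to 5.69) of those in the comparison by number.

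WT FOXA1 regions called in both libraries overlapped 71.5% of gained, 99.4% of kept and 99.3% of lost regions. A FOXA1 peak of either WT library overlapped 90.15% of gained, 99.84% of kept and 99.79% of lost regions. Within 1 kb of a gene end lay 1.82% of lost, 4.31% of kept and 3.75% of gained FOXA1 regions. Chromosome 12 held 14.7% and 12.1% of FOSL2 peaks with doxycycline and 7.12% and 9.43% without it, and 9.85% and 10.8% against 7.87% and 7.62% of FOXA1 peaks.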
